A study of Homo sapiens with 6 samples.

How the data were processed

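Total RNA of HepG2 cells was profiled 48 hours after transfection with a control siRNA or 1 of 2 siRNAs against beta-catenin, 2 samples per group. Per the labels, RNA was labelled with Cy3 and each sample was read on 1 array. Per the file headers and the submitters' processing notes, the arrays were extracted with Agilent Feature Extraction 10.7.3.1 under a 1-colour gene expression protocol, with the grid annotated on hg19. Per the file headers, the deposited intensity of each spot (the processed signal) had its background subtracted and was detrended within the array, and dim spots carry a small positive surrogate value, so that low signals are compressed. The deposited median intensity of each spot and of its local background was taken before that subtraction. Per the file headers, the other deposited columns are 0 or 1 marks for spots well above background, saturated, or outlying. No spot was saturated, and 298 to 387 spots per array were marked as outliers.

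The authors' table of processed values holds log2 values. Set against the scanner files over 21368 probes with 1 spot, its differences between arrays equalled those of log2 processed signal up to 1 constant per array. Its column medians were -0.10 and -0.10 (siCtrl), -0.06 and -0.08 (siBcat9) and 0.11 and 0.03 (siBcat10). Its scale is therefore log2 and its direction that of the signal, while the value on which each probe was centred stays unknown. It was used as an alternative only.

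For the main values, log2 of the processed signal was taken and each array's 75th percentile over its 58717 non-control spots was subtracted. The 4259 control spots were left out, outlier spots were set to missing, and spots of a probe were averaged (34085 probes had 1 spot, 7321 had 2 and 999 had 10). A probe was kept if well above background on both arrays of at least 1 group: of 42405 probes, 14675 were dropped as dim and 2 for missing values, and 27728 were kept. The files hold no gene symbol column, so accessions were named through the RefSeq genes of assembly GRCh38.p14, without versions, used for names only: 26364 probes matched 19796 symbols and 16041 kept the identifier of the files. A gene was represented by its kept probe with the highest mean signal, which gave 22556 genes, 14602 with a symbol and 7954 without. Among 5172 other kept probes, 1640 were called together with their gene's representative in the mean comparison, 94 of them in the opposite direction. No coordinates are taken from RefSeq.

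All 6 arrays entered 1 limma model with a mean per group and a shared spread (3 residual degrees of freedom, prior degrees of freedom 2.75, prior SD 0.12 on the log2 scale). Moderated tests with eBayes compared siBcat9 with siCtrl, siBcat10 with siCtrl, the mean of both with siCtrl, and siBcat9 with siBcat10. P-values were adjusted by the Benjamini-Hochberg method within each comparison over all genes, with a threshold of 0.05. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own. The lowest such signals ranged from -8.36 to -6.92 on the log2 scale relative to the 75th percentile. The bound is not strict, because the true signal of a dim gene may lie above both of these values. The fold marked "at least" can then be too large. The lists of 21 gene groups were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists, again with an estimated correlation, and with fry. No list call below the threshold with the preset correlation held with an estimated one. With an estimated correlation camera's test rests on the 3 residual degrees of freedom, which leaves it little power. For the Wnt list in the mean comparison the estimated correlation, -0.0108, lay below the preset one. Yet its unadjusted camera p rose from 6.39e-12 to 0.00469. The lost calls therefore do not show that correlation between genes produced them. Fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, gave adjusted p-values from 7.28e-05 to 0.0167 for the 12 lists that camera called in the mean comparison. Fry also passed lists that camera did not call: pericentral genes (0.00105, direction down), other cell types (0.00214) and acute phase genes (0.00352). The cadherin, catenin and desmosome list (0.00435, direction up), Wnt pathway components (0.0167) and long non-coding RNAs (0.044) passed as well. The fetal liver (0.181), stress response (0.539) and reference lists (0.244) did not pass. Fry therefore does not single out the 12 lists.

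Samples were grouped by their labels. The genes named were fixed by rule before the data were examined, as were the groups, gene lists, tests and most alternatives: CTNNB1; the 12 highest and 12 lowest genes called by both siRNAs in 1 direction with no overlap between knockdown and control arrays, by the smaller change; the 5 highest and 5 lowest of each siRNA; the 8 highest and 8 lowest between the siRNAs with no overlap; and up to 4 genes of each list with the lowest adjusted p. Apart from CTNNB1 and the lists, only genes with a symbol were eligible. Other list members were chosen after their values were seen: RNF43, ZNRF3, CCND1, PPARD, FBP1, PON1, TBX3, EPHB2, PROX1, ALB, APOB, ABCC2, CYP7A1, NQO1, NDRG1, ALDOC, EGLN3, PFKFB4, E2F1, CCNE1, OAS1, OAS3, TGFBI, KRT19 and GLUL. Of the Wnt list AXIN2 and LGR5 were named by the pericentral list. Some genes that the rule names are not reported here.

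Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median of kept probes, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, the mean over a gene's probes, every probe on its own, the authors' table, the replicate number as a block, only the groups compared, eBayes with a trend or robust, and each sample left out in turn. Normexp was planned on the mean spot signal, and the median spot signal was used because the files carry no mean column. A slide block was planned and not fitted, since all arrays lay on 1 slide and 1 scan.

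The model was tested on simulated arrays with the measured means and spreads of 22556 genes, 200 of them changed. In the mean comparison, 23.9%, 82.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 8.05% false calls. For siBcat9 alone the shares were 5.97%, 77.6% and 98.5%, with 5.47% false calls. For siBcat10 alone they were 4.48%, 70.1% and 98.5%, with 6.50% false calls. In the measured data 44.5% of genes were called in the mean comparison. With only 200 genes changed, the adjusted threshold is stricter than there, so the recovered shares do not carry over to these data. Camera called a simulated list of 25 genes shifted by 0.5 and 0 of 20 unshifted lists. Genes were drawn independently there, whereas the estimated correlation reached 0.454 in the measured stress response list. False calls of lists with correlated genes were therefore not tested. R 4.3.3, limma 3.58.1, data.table (1.17.8) and matplotlib 3.10.9 were used.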

Results

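Gene expression was measured in HepG2 cells, a human liver cancer line of hepatoblast-like character in which beta-catenin is stabilised by a deletion in its gene, CTNNB1. Beta-catenin is both a partner of cadherins at cell junctions and the transcriptional co-activator of the Wnt pathway. The cells were transfected for 48 hours with a control siRNA (siCtrl) or with either of 2 independent siRNAs against beta-catenin, number 9 (siBcat9) and number 10 (siBcat10). Each group held 2 samples, and each sample was hybridised to its own 1-colour array, 6 arrays in all. The arrays carried 58717 non-control spots, of which 64.5% to 69.5% per array lay well above background, and the 75th percentile of the processed signal ranged from 792 to 1096. Across the genes tested, with 1 probe each and dim probes left out, the samples of a group correlated at r = 0.997 for siCtrl and 0.996 for siBcat9 and siBcat10. Between control and knockdown arrays r was 0.973 to 0.981. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples, and their number limits the precision of every value. All 6 arrays lay on 1 slide, and each group filled its own column of that slide, so column and group cannot be told apart.

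The first question was whether both siRNAs lowered their target. CTNNB1 mRNA, the transcript of NM_001904, fell to 4.99% of the control signal with siBcat9 and to 9.28% with siBcat10. Its log2 signal relative to the array's 75th percentile was 2.94 ± 0.10 (SD, n = 2) in siCtrl, -1.39 ± 0.0035 (SD, n = 2) in siBcat9 and -0.49 ± 0.05 (SD, n = 2) in siBcat10. In limma's moderated test the log2 change was -4.33 (SE 0.09, adjusted p = 2.15e-05) for siBcat9 and -3.43 (SE 0.09, adjusted p = 6.79e-05) for siBcat10. CTNNB1 was 1.86-fold lower with siBcat9 than with siBcat10 (adjusted p = 0.00663). A second CTNNB1 probe gave log2 changes of -5.10 and -4.40.

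**Figure D1:**
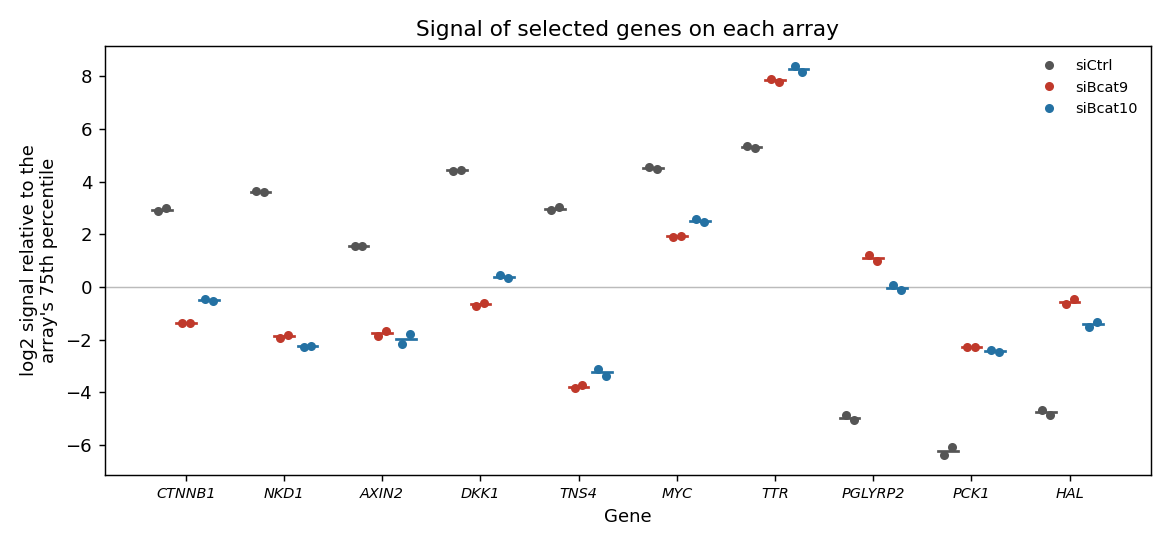
Signal of 10 genes on each array, as log2 of the processed signal relative to the array's 75th percentile; points are single arrays (2 per group), bars their means, and levels can be compared within a gene only. CTNNB1, NKD1, AXIN2, DKK1, TNS4 and MYC lie lower on all 4 knockdown arrays than on both control arrays, and TTR, PGLYRP2, PCK1 and HAL lie higher.

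The main comparison asked which genes both siRNAs changed in the same direction. Among the 12 genes with the largest shared falls, TNS4, an adaptor protein of focal adhesions, was 108-fold lower with siBcat9 (log2 change -6.76, SE 0.12) and 74.4-fold lower with siBcat10 (log2 change -6.22, SE 0.12). NKD1, a feedback inhibitor of Wnt signalling, was 45.3-fold and 58.9-fold lower. LGR5, the R-spondin receptor, was 24.5-fold lower with siBcat9 and, not well above background on either siBcat10 array, at least 38.9-fold lower with siBcat10. The synaptic complexin CPLX2 fell 56.5-fold and 44.0-fold (log2 changes of a second probe -3.79 and -3.37), the hyaluronan-degrading CEMIP 57.1-fold and 24.1-fold (second probe -2.55 and -2.97), the cytokine gene IL11 60.3-fold and 23.5-fold, and the glucose transporter SLC2A3 28.8-fold and 41.1-fold. The sulfatase gene ARSI (33.1-fold and 25.2-fold), the potassium channel gene KCNJ10 (23.7-fold and 26.4-fold) and KRTAP3-1 (26.8-fold and 27.8-fold, second probe -6.06 and -5.72 on the log2 scale) completed the measured set. The neurotrophin receptor gene NGFR fell 51.2-fold and 32.2-fold, with 1 of the 2 arrays of each knockdown group well above background. ASB4 was not well above background in either knockdown group and was at least 25.9-fold and at least 21.4-fold lower, with log2 changes of -3.59 and -3.25 for a second probe. Adjusted p-values of these 12 genes ranged up to 0.000199 for siBcat9 and 0.000347 for siBcat10, and all 4 knockdown arrays lay below both control arrays for each. The folds and the bounds hold for the scanner files' own background correction. After normexp, where an offset of 50 added to every signal shrinks the ratios of dim genes, the log2 changes were -1.74 and -1.44 for ASB4, -2.17 and -2.09 for LGR5, -2.81 and -2.50 for NGFR, -3.80 with siBcat9 for CEMIP and -3.07 with siBcat10 for KCNJ10.

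Among the 12 genes with the largest shared rises, several encode liver products. PGLYRP2, a secreted amidase of the liver that cleaves peptidoglycan, rose 67.0-fold with siBcat9 (log2 change 6.07, SE 0.14, adjusted p = 2.15e-05) and 30.9-fold with siBcat10 (log2 change 4.95, SE 0.14, adjusted p = 6.79e-05). G6PC1, the catalytic subunit of the enzyme that releases free glucose, rose 33.1-fold and 14.1-fold, and PCK1, the cytosolic carboxykinase of gluconeogenesis, rose 15.4-fold and 13.7-fold. The urea cycle arginase ARG1 rose by 3.42 and 3.61 on the log2 scale. F13B, a coagulation factor subunit, was not well above background in siCtrl and was at least 18.3-fold and at least 16.9-fold higher. The gastrin gene GAST rose 21.4-fold and 11.1-fold, LGI4 11.9-fold and 24.9-fold, and FXYD1, a regulator of the sodium pump, rose by 3.45 and 3.46 on the log2 scale. CTSO (at least 8.68-fold and at least 11.1-fold), FAM47E (at least 9.67-fold and at least 9.40-fold) and GBP3 (at least 7.88-fold and at least 8.44-fold) were also not well above background in siCtrl. Adjusted p-values of these genes reached at most 0.00132. After normexp the log2 changes were 1.18 and 1.25 for F13B, 0.79 and 1.01 for CTSO, 0.62 and 0.76 for FAM47E, 0.70 and 0.86 for GBP3, 2.97 and 1.97 for G6PC1, and 1.85 and 1.82 for PCK1.

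Of 22556 genes tested, 9532 passed an adjusted p of 0.05 with siBcat9 (5424 higher, 4108 lower), and 8884 passed with siBcat10 (5346 higher, 3538 lower). In the mean of both siRNAs against siCtrl, 10036 genes passed, 5910 higher and 4126 lower, of which 1296 rose and 859 fell by at least 2-fold. The 2 siRNAs shared 6083 calls in the same direction, 3728 higher and 2355 lower, where independent lists of these sizes would share 1286 and 644. A further 110 genes were called in opposite directions, but 18 without either siCtrl replicate, 71 and 57 without siBcat9 replicate 1 and 2, 224 without siBcat10 replicate 2, 27 with dim probes kept and 192 after normexp. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.80 and rho = 0.73. Simulations of noise alone, in which both unchanged groups were set against the same simulated controls, gave 0.50 and 0.47. They shared on average 0 calls and at most 1, which simulating noise alone fixes beforehand, so this count does not test the overlap. No shift of a group or slide column was simulated. The covariance was 0.389 against a simulated 0.0143, a difference of 0.375. The simulated values already hold the noise of shared controls at each gene's measured spread. A shift common to both control arrays is not in them, and 2 control arrays cannot be split into 2 sets of at least 2. Part of the excess over these values may therefore come from such a shift.

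These counts rest on few arrays and on the scaling. Without siCtrl replicate 1 the counts were 6322 (siBcat9), 4898 (siBcat10), 6069 (mean) and 3566 (both siRNAs), and without siCtrl replicate 2 they were 5129 (siBcat10), 6250 (mean) and 3665 (both siRNAs). The median log2 change of all genes was 0.10 with either siRNA, to which single changes can be compared, and after a normexp background correction it was 0.21 with siBcat10, where the share of calls that were higher rose from 60.2% to 73.8% (13417 calls, 9906 higher), and in the mean comparison from 58.9% to 69.4%. The share fell with other scalings: with siBcat9 from 56.9% to 50.3% after quantile normalization and to 48.4% (4530 higher, 4822 lower) with the median of kept probes, and in the mean comparison to 52.8% and 52.1%.

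Genes known as targets or feedback regulators of the Wnt pathway fell together. Of 24 measured members of this list, fixed beforehand, 19 fell and 1 rose in the mean of both siRNAs (20 fell and 1 rose adjusted over the list alone), with a median log2 change of -1.55, or -1.51 with its 2 genes near background at their bounds. Camera gave an adjusted p = 1.34e-10 (adjusted p = 0.0561 with an estimated correlation). The feedback genes AXIN2 (log2 change -3.42, SE 0.13), DKK1 (-4.56, SE 0.09) and SP5 (-2.34, SE 0.07) fell, as did the proto-oncogene MYC (-2.29, SE 0.08) and the ubiquitin ligases RNF43 (-2.18) and ZNRF3 (-1.84), which remove Wnt receptors. CCND1 fell by 0.72 on the log2 scale, and the nuclear receptor gene PPARD was the member that rose, by 0.65 (0.30 with a second probe).

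Genes typical of periportal hepatocytes rose: 13 of 17 measured members rose and 1, FBP1, fell (13 and 1 adjusted over the list alone), with a median log2 change of 1.22 and a camera adjusted p = 1.71e-05 (adjusted p = 0.164 with an estimated correlation). FBP1 (log2 change -0.85, adjusted p = 0.0374) lost its call with dim probes kept, with a trend in eBayes and after normexp (0.09). It also lost it without siCtrl replicate 1 (-0.74), siCtrl replicate 2 (-0.97), siBcat9 replicate 2 (-0.69) or siBcat10 replicate 2 (-0.69). It was not among the genes called with the filter on all 6 arrays. HAL, which degrades histidine, rose 13.7-fold and the E-cadherin gene CDH1 11.3-fold. Of 17 pericentral genes, many of them beta-catenin dependent in liver, 7 rose and 6 fell (7 and 6 adjusted over the list alone). Their median log2 change of 0.09 differed in sign from their mean of -0.39 and from the direction of camera, which was down (adjusted p = 0.504). The median was 0.0085 without siCtrl replicate 2, 0.177 without siCtrl replicate 1, 0.174 without siBcat9 replicate 1, 0.165 without siBcat10 replicate 1, 0.218 without siBcat10 replicate 2, 0.333 with dim probes kept, 0.142 after normexp, 0.0438 after quantile normalization and 0.0398 with the median of kept probes. SLC13A3, a dicarboxylate transporter gene, fell 8.03-fold (log2 change of a second probe -2.33) and AHR 2.22-fold, whereas PON1 rose 5.95-fold (log2 change 0.86 after normexp; not tested with the filter on all 6 arrays). AXIN2, LGR5, TBX3 and EPHB2 stand in both this list and the Wnt list.

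Most hepatocyte genes rose. Of 25 secreted proteins and transcription factors of hepatocytes, 20 rose and PROX1 fell (20 and 1 adjusted over the list alone), with a median of 0.74 and a camera adjusted p = 8.73e-06 (adjusted p = 0.228 with an estimated correlation). PROX1 lost its call with dim probes kept and without siCtrl replicate 1 (log2 change -0.46), siCtrl replicate 2 (-0.63) or siBcat9 replicate 1 (-0.48). Transthyretin (TTR) rose 6.72-fold, the fibrinogen chain gene FGB 6.36-fold, APOC3 5.93-fold, the transcription factor gene ONECUT1 4.18-fold and albumin (ALB) 2.28-fold, while APOB did not pass (adjusted p = 0.992). Of 14 genes of bile acid synthesis and transport, 11 rose and ABCC2 fell (12 and 1 adjusted over the list alone), with a median of 1.81 (1.16 after normexp) and a camera adjusted p = 2.96e-05 (adjusted p = 0.164 with an estimated correlation). The transporter genes SLC51A and SLC10A1 rose 13.6-fold and 6.12-fold, and the synthesis genes AKR1D1, CYP8B1 and CYP7A1 rose 7.75-fold, 4.58-fold and 4.21-fold. After normexp the log2 changes were 1.25 for SLC10A1, 1.86 for AKR1D1 and 0.77 for CYP7A1. Of 12 genes of xenobiotic metabolism, 11 rose and NQO1 fell (11 and 1 adjusted over the list alone), with a camera adjusted p = 0.000379 (adjusted p = 0.164 with an estimated correlation). NQO1 lost its call without siCtrl replicate 2 (log2 change -0.52). CYP3A7 and CYP3A5 rose 6.60-fold and 6.40-fold, although a second CYP3A5 probe gave a log2 change of 0.52, and of -0.66 with siBcat10 alone (adjusted p = 0.0105), and normexp gave 1.76 for the mean. CYP2D6 rose 2.47-fold and AKR1C1 1.96-fold.

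Fetal liver and hepatoblastoma genes went both ways. Of 17 measured, 5 rose (3 without siCtrl replicate 1) and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.975), with the alpha-fetoprotein gene AFP 2.93-fold and PEG10 1.74-fold higher, and GREB1 2.15-fold and SALL4 1.59-fold lower (log2 change -0.24 after normexp). Of 14 acute phase and complement genes, 6 rose (11 after normexp) and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.14). The heme-binding hemopexin (HPX) and SAA4 rose 4.39-fold and 3.84-fold, and the iron hormone gene HAMP and SERPINA3 fell 5.28-fold and 3.06-fold (log2 changes of other SERPINA3 probes -2.22 and -2.12).

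Genes of lipid synthesis and of glycolysis were compared next. In the cholesterol synthesis list 17 of 21 members rose and 1 fell (17 and 1 adjusted over the list alone; 0 fell with dim probes kept and without siCtrl replicate 1, siCtrl replicate 2, siBcat9 replicate 1 or siBcat9 replicate 2), with a median of 0.72 and a camera adjusted p = 1.71e-05 (adjusted p = 0.164 with an estimated correlation). MVD rose 2.66-fold, MVK 2.48-fold, LSS 2.47-fold (log2 change of a second probe 1.94) and HMGCS1 2.12-fold. In the fatty acid synthesis list 10 of 14 rose and 0 fell (11 and 0 adjusted over the list alone; 1 fell after normexp), with a camera adjusted p = 0.000615 (adjusted p = 0.183 with an estimated correlation). PNPLA3 rose 2.64-fold, LPIN1 2.53-fold (log2 change of a second probe 0.67), MLXIPL 2.43-fold and ELOVL6 2.37-fold. Of 20 glycolysis and hypoxia genes, 15 fell and 4 rose (15 and 4 adjusted over the list alone), with a median of -0.48 and a camera adjusted p = 9.79e-05 (adjusted p = 0.228 with an estimated correlation). The glucose transporter SLC2A1 fell 6.15-fold, the regulator PFKFB3 4.19-fold and the hexokinase HK2 2.64-fold, where second probes of PFKFB3 and HK2 gave log2 changes of -1.10 and -2.06. NDRG1, ALDOC, EGLN3 and PFKFB4 were the members that rose. Only 9 members fell with dim probes kept, without siCtrl replicate 1 or without siBcat9 replicate 1, and 2 rose without either siCtrl replicate, where EGLN3 (log2 changes 0.45 and 0.44) and PFKFB4 (0.37 and 0.35) lost their call. PFKFB4 also lost it with dim probes kept and without siBcat9 replicate 2 (0.34).

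S phase and mitosis genes fell: 23 of 28 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 change of -0.74 and a camera adjusted p = 1.08e-09 (adjusted p = 0.0561 with an estimated correlation). The replication helicase genes MCM2, MCM5 and MCM3 fell 2.27-fold, 2.08-fold and 1.90-fold, and the mitotic kinase gene BUB1 fell 1.80-fold. E2F1 and CCNE1 did not pass (adjusted p = 0.355 and 0.46). Of 16 p53 targets, 6 fell and 3 rose (8 and 3 adjusted over the list alone), with a median of -0.24 and a camera adjusted p = 0.0275 (adjusted p = 0.23 with an estimated correlation; adjusted p = 0.0628 after quantile normalization). By siRNA, only siBcat10 passed in camera (median -0.40, adjusted p = 0.00231), and siBcat9 did not (median 0.04, adjusted p = 0.553). PLK3, GADD45A and CDKN1A fell 2.52-fold, 1.99-fold and 1.66-fold, and TP53INP1 rose 4.27-fold. Of 16 integrated stress and unfolded protein response genes, 6 rose and 5 fell (7 and 6 adjusted over the list alone), with a median of 0.25, a mean of -0.12 and a camera adjusted p = 0.722 with direction down. Without siCtrl replicate 1, siCtrl replicate 2 and siBcat9 replicate 1 in turn, 2, 1 and 2 rose, 1 rose with dim probes kept, and 3 fell without siCtrl replicate 1. ATF3 and SLC7A11 fell 2.54-fold and 2.17-fold, CHAC1 fell 2.13-fold and PHGDH rose 1.65-fold; of 3 other ATF3 probes, 1 gave a log2 change of 0.16 that did not pass.

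Interferon-stimulated genes, which double-stranded RNA can induce, mostly rose: 13 of 18 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.98 (0.619 after normexp) and a camera adjusted p = 0.00279 (adjusted p = 0.164 with an estimated correlation). Only 18 of the 24 listed genes were measured, without RSAD2, CXCL10, HERC5, IFI44, IFI44L and IFI27. The control cells were transfected with an siRNA too, so the comparison does not test a response to double-stranded RNA. IFIT3, IFIT1 and XAF1 rose 6.08-fold, 5.91-fold and 5.08-fold and MX1 2.22-fold (log2 change of XAF1 1.60 with a second probe and 1.03 after normexp), whereas OAS1 and OAS3 fell 1.82-fold and 1.29-fold (1 member fell without either siCtrl replicate). OAS3 lost its call with dim probes kept and without siCtrl replicate 1 (log2 change -0.40), siCtrl replicate 2 (-0.34), siBcat9 replicate 1 (-0.33), siBcat9 replicate 2 (-0.41) or siBcat10 replicate 1 (-0.30). Targets of TGF-beta and YAP and mesenchymal genes fell in 10 of 15 cases and TGFBI rose (10 and 1 adjusted over the list alone), with a median of -0.71 (-0.465 with dim probes kept, -0.475 after normexp) and a camera adjusted p = 3.74e-05 (adjusted p = 0.164 with an estimated correlation). The count of 1 that rose was 2 after normexp and without siBcat10 replicate 2, and 0 without siCtrl replicate 1, where TGFBI (log2 change 0.48) lost its call. CCN1 fell 15.0-fold, ANKRD1 5.16-fold, TAGLN 4.67-fold and THBS1 2.45-fold.

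Of 17 cadherin, catenin and desmosome genes, 6 rose and 6 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.722), with a median of -0.0121, a mean of 0.13 and camera direction down; the median ranged from -0.0648 with the median of kept probes to 0.0442 without siBcat10 replicate 2. It was 0.000629 without siCtrl replicate 2, -0.0334 and 0.00918 without siBcat9 replicate 1 and 2, and -0.0587 without siBcat10 replicate 1. The largest change in this list was the rise of CDH1 (log2 change 3.50), which also stands in the periportal list. JUP, which encodes the beta-catenin relative plakoglobin, and NECTIN2 rose 2.15-fold and 1.59-fold, and DSC2 fell 1.70-fold; a second NECTIN2 probe did not pass (log2 change 0.23). Of 26 Wnt pathway components that act with or on beta-catenin, 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.939); the receptor genes FZD1, FZD2 and FZD5 rose 2.89-fold, 2.13-fold and 1.53-fold, and WNT11 fell 1.60-fold (log2 changes of FZD1 and WNT11 after normexp 0.96 and -0.32). Without siCtrl replicate 1 or 2, 4 or 3 of them rose and 2 fell, and 2 fell with dim probes kept. Of 13 named long non-coding RNAs, 3 rose (6 after normexp or with a trend in eBayes, 5 with the mean over probes or the filter on all 6 arrays) and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.722), with a median of -0.19, a mean of 0.13 and camera direction down; the median was 0.0304 after normexp, 0.0213 with dim probes kept and 0.0981 with the mean over probes, and it was -0.0363 without siCtrl replicate 2 and -0.116 without siBcat9 replicate 2. HULC, LINC00261 and KCNQ1OT1 rose 2.97-fold, 2.87-fold and 1.83-fold, and CYTOR fell 1.92-fold. Of 12 markers of other cell types, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.132): PECAM1, CD14 and VWF rose 2.84-fold, 1.93-fold and 1.86-fold, and KRT19 fell 1.53-fold (log2 changes of PECAM1 and VWF after normexp 0.90 and 0.48). Of 12 commonly used reference genes, B2M rose 1.38-fold and HPRT1 fell 1.45-fold (1 and 1 adjusted over the list alone; camera adjusted p = 0.411; 2 rose without siBcat10 replicate 2, 2 fell without siBcat9 replicate 2 or siBcat10 replicate 1, and 2 rose and 4 fell after normexp). TBP and ACTB had log2 changes of -0.30 and -0.24, with adjusted p of 0.0516 and 0.0603; both passed after normexp and after scaling to the median of kept probes, and B2M did not pass without siCtrl replicate 2 (log2 change 0.40).

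**Figure D2:**
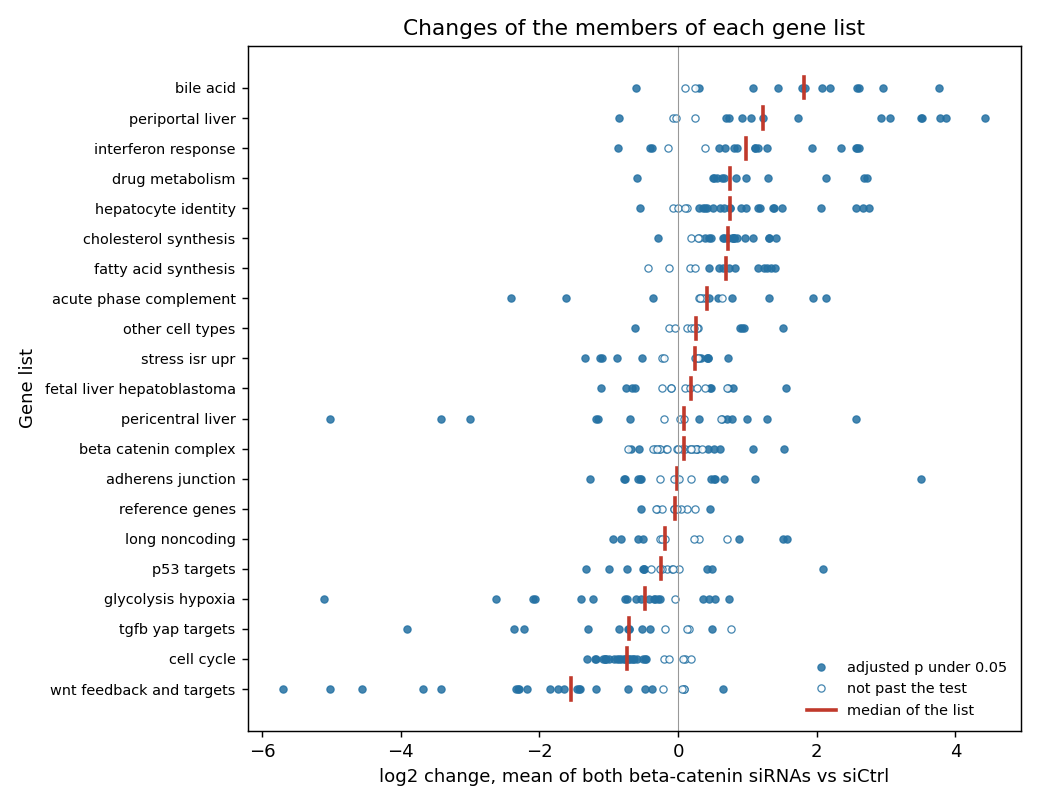
Log2 change of each measured member of the 21 gene lists in the mean of both beta-catenin siRNAs against siCtrl (horizontal axis), 1 list per line; filled points passed an adjusted p of 0.05, open points did not, and the red bar is the list's median. The medians run from -1.55 for the Wnt targets to 1.81 for the bile acid genes.

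Among the 5 highest and 5 lowest genes of each siRNA, few lay beyond the shared ones named above. Of all calls, 63.8% with siBcat9 and 68.5% with siBcat10 were also called in the same direction with the other siRNA. With siBcat9, the phospholipase gene PLA2G1B and KNG1, the gene for the plasma protein kininogen, stood among the 5 largest rises, 25.5-fold each (log2 change 4.67, SE 0.10, adjusted p = 2.15e-05 for PLA2G1B). With siBcat10 they rose 6.07-fold and 9.21-fold, less than with siBcat9 (adjusted p of the difference 0.00253 and 0.00448). The glucosidase gene GBA3, well above background on 1 of 2 control arrays, and SLC51A stood among the 5 largest rises with siBcat10, 20.1-fold and 17.8-fold. With siBcat9 these rose 6.56-fold and 10.5-fold (adjusted p of the difference 0.0129 and 0.015). After normexp the log2 change of GBA3 with siBcat10 was 1.71. The 5 largest falls of either siRNA were all among the 12 shared falls above.

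Comparing the 2 beta-catenin siRNAs with each other asks where they differed. Of 22556 genes, 4524 passed (2187 higher and 2337 lower with siBcat9), 684 of them by at least 2-fold. BAAT, which conjugates bile acids, was well above background only on the siBcat9 arrays and was at least 11.6-fold higher there (adjusted p = 0.00907). The integrin gene ITGB3 was at least 4.18-fold higher with siBcat9, PLCE1 at least 4.44-fold (log2 difference of a second probe 1.16, adjusted p = 0.125), TTLL6 at least 2.90-fold and LGSN at least 1.69-fold, also well above background with siBcat9 alone. SOBP was 4.72-fold, CAMTA1 5.10-fold and the aquaporin gene AQP11 4.49-fold higher with siBcat9. PSAPL1 was 13.2-fold higher with siBcat10 (log2 difference, siBcat9 minus siBcat10, of -3.73, SE 0.16, adjusted p = 0.00241), RASGRP2 7.42-fold and TINAG at least 5.86-fold. NRARP, CEROX1, ITGA10, KREMEN2 and VGF, which fell with both siRNAs, lay 5.92-fold, 5.69-fold, 5.49-fold, 5.14-fold and 5.07-fold lower with siBcat9. Of these genes, PSAPL1, CAMTA1 and AQP11 were called against siCtrl in opposite directions by the 2 siRNAs. For CAMTA1 this was lost after normexp, with dim probes kept and without siCtrl replicate 1 or siBcat10 replicate 1, and PSAPL1 was not tested with the filter on all 6 arrays. A second CAMTA1 probe was not called with siBcat10 (log2 change -0.28, adjusted p = 0.223) and gave a difference of 1.34. After normexp the log2 differences were 1.15 for BAAT, 0.28 for ITGB3, 0.51 for PLCE1, 0.76 for CAMTA1, -1.65 for PSAPL1, -0.77 for TINAG and -1.41 for CEROX1.

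Among the gene lists, 8 differed between the siRNAs in camera. The acute phase and complement genes were higher with siBcat9 in 8 of 14 cases and lower in 0 (10 and 2 adjusted over the list alone; median difference 0.63, adjusted p = 0.000305; adjusted p = 0.258 with an estimated correlation), as were pericentral genes in 6 of 17, with 1 lower (7 and 1 adjusted over the list alone; 0.48, adjusted p = 0.00113; adjusted p = 0.258 with an estimated correlation) and interferon-stimulated genes in 6 of 18, with 0 lower (8 and 0 adjusted over the list alone; 0.45, adjusted p = 0.00133; adjusted p = 0.258 with an estimated correlation). The glutamine synthetase gene GLUL had log2 changes against siCtrl of 0.79 with siBcat9 and -0.73 with siBcat10, neither of which passed (adjusted p = 0.0664 and 0.086), and their difference passed (adjusted p = 0.0201) but not with dim probes kept and without siBcat9 replicate 2 (1.23) or siBcat10 replicate 1 (1.25). The p53 targets were higher with siBcat9 in 9 of 16 cases and lower in 1 (10 and 3 adjusted over the list alone; 0.41, adjusted p = 0.0154; adjusted p = 0.357 with an estimated correlation). Of 17 periportal genes 6 were higher and 0 lower (6 and 0 adjusted over the list alone; 0.19, adjusted p = 0.0226; adjusted p = 0.482 with an estimated correlation), and of 25 hepatocyte genes 8 and 0 (9 and 2 adjusted over the list alone; 0.13, adjusted p = 0.041; adjusted p = 0.672 with an estimated correlation). Of 21 cholesterol synthesis genes 4 were higher and 0 lower (5 and 0 adjusted over the list alone; 0.14, adjusted p = 0.0371; adjusted p = 0.499 with an estimated correlation), and of 28 cell cycle genes 1 was higher and 7 lower (1 and 7 adjusted over the list alone; -0.20, adjusted p = 0.0371; adjusted p = 0.347 with an estimated correlation). The Wnt list did not pass (median difference 0.10, adjusted p = 0.61). The number of genes that differed between the siRNAs was 974 without siBcat9 replicate 1, 731 without siBcat9 replicate 2, 1183 without siBcat10 replicate 1, 2727 without either siCtrl replicate and 850 with dim probes kept. Among the genes named, TTLL6 and LGSN lost their call with dim probes kept and with normexp (log2 differences 0.19 and 0.13), without siBcat9 replicate 1 (2.45 and 2.17), without siBcat9 replicate 2 (2.06 and 2.14) and without siBcat10 replicate 1 (1.97 and 2.22), and LGSN also without siBcat10 replicate 2 (2.09). BAAT lost it without siBcat9 replicate 2 (3.68), and PLCE1 without siBcat9 replicate 2 (2.14) or siBcat10 replicate 1 (2.27).

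**Figure D3:**
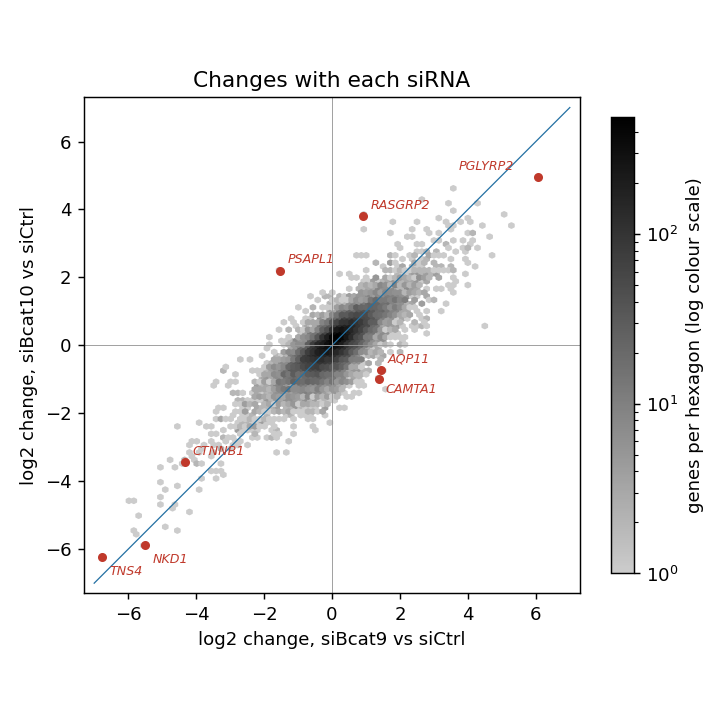
Log2 change of each of 22556 genes with siBcat9 (horizontal axis) and with siBcat10 (vertical axis), both against siCtrl; shading is the number of genes per hexagon on a log colour scale, the blue line marks equal changes, and named genes are red. CTNNB1 lies at -4.33 and -3.43, and PSAPL1, CAMTA1 and AQP11 lie in the quadrants of opposite signs.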

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

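For the pattern weighed here, the tests of knockdown strength and of slide position were chosen after the result was seen. The results below drew attention because the effects of the 2 siRNAs against the same control differed in limma's or camera's test of the difference.

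CTNNB1 itself differed by -0.90 on the log2 scale (siBcat9 minus siBcat10). Among the shared falls, TNS4 (-0.54), ARSI (-0.40), CEMIP (-1.24) and IL11 (-1.36) fell further with siBcat9, though a second CEMIP probe gave a difference of 0.42 that did not pass (adjusted p = 0.102), and NKD1 (0.38) fell further with siBcat10. Among the shared rises, PGLYRP2 (1.11), G6PC1 (1.23) and GAST (0.94) rose more with siBcat9, and LGI4 (-1.07) rose more with siBcat10. PSAPL1 (-3.73), CAMTA1 (2.35) and AQP11 (2.17) went in opposite directions, the fall of CAMTA1 with siBcat10 on 1 of its 2 probes only, as did 110 genes in all (18 without either siCtrl replicate), 44 higher and 66 lower with siBcat9, each past the threshold in the test of the difference. After normexp the differences were -1.65 for PSAPL1 and 0.76 for CAMTA1.

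Median differences of gene lists were 0.48 for pericentral, 0.185 for periportal, 0.126 for hepatocyte, 0.629 for acute phase and complement, 0.143 for cholesterol synthesis, 0.451 for interferon-stimulated and 0.406 for p53 target genes, and -0.198 for cell cycle genes. All 8 calls were lost with an estimated correlation (adjusted p of 0.258 to 0.672).

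The pattern weighed was the 4524 genes that differed between the siRNAs. The siBcat10 arrays were dimmer, but quantile normalization, which gives every array the same distribution of signals, called 4799 genes, 4071 of them shared with the 4524, which argues against a trend with signal as the whole cause. Stronger knockdown with siBcat9 could enlarge changes. Of 2812 genes called both between the siRNAs and in the mean comparison, 76.0% (exact binomial 95% interval 74.4% to 77.6%) changed more with siBcat9. That leaves the explanation open for them. The other 675, or 24.0% (22.4% to 25.6%), are the remainder of the same count, not a second test. They changed more with siBcat10, which argues against it for those that are not false calls. The 5% of false calls allowed holds over all calls of a comparison, so it does not give their number here. The Wnt list did not differ between the siRNAs in camera (adjusted p = 0.61), with 3 of 24 members higher and 4 lower with siBcat9. Its mean log2 change was -1.79 with siBcat9 and -1.8 with siBcat10, and its median -1.66 and -1.43. Array position cannot be told apart from the groups, as 0 of 3 slide columns held more than 1 group. Effects of each siRNA on other transcripts were not tested and stay open.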

How the results depend on the processing

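Depth here is signal over background: genes near it have only bounds, and keeping dim probes (34424 genes tested) lowered the counts to 5848 for siBcat10, 4039 for both siRNAs and 850 between the siRNAs. Normexp raised the siBcat10 count to 13417, and the median log2 change of all genes with siBcat10 from 0.10 to 0.21. Its offset of 50 was the same on every array. The 75th percentile of the processed signal was lower with siBcat10 (792 and 912) than with siCtrl (1096 and 1076). Relative to that percentile, the offset can lift dim genes more with siBcat10. Part of the added higher calls can therefore come from this step, and how large a part was not tested. With only the groups compared in the fit, 2727 genes differed between the siRNAs. No cause of these shifts was tested. The settings themselves bring the offset, the added dim genes and the fewer samples. With an estimated correlation the adjusted p was 0.0561 for the Wnt list, 0.0561 for the cell cycle list and 0.228 for the hepatocyte list, the highest over all settings run, in which the lowest were 1.15e-13, 7.92e-14 and 2.67e-07, and none of the 12 list calls in the mean comparison held. The p53 list was also lost with quantile normalization (0.0628; at most 0.23 over the settings), and the markers of other cell types passed with every probe on its own (0.0478; at most 0.43 over the settings).

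Leaving out 1 array leaves its group with 1 sample, assumed to vary like the others. The counts then ranged from 6322 to 10038 for siBcat9, 4898 to 8294 for siBcat10, 6069 (without siCtrl replicate 1) to 10273 for the mean, 3566 to 5545 for both siRNAs and 731 to 4490 between the siRNAs. In all settings run, CTNNB1 kept its direction and its call with both siRNAs, and the correlation of changes across genes stayed within 1.5 times its value. Of 151 results for genes named by a fixed rule, 144 kept direction and call in every setting where they were tested, but 23 were not tested with the filter on all 6 arrays, and 42 shrank by more than 1.5 times after normexp. The exceptions were TTLL6, LGSN, BAAT, PLCE1, B2M (lost without siCtrl replicate 2), TBP and ACTB (called in some settings), with 0 calls reversed among these genes and the lists. List members named after their values were seen are not among the 151. Of those, FBP1, PROX1, NQO1, TGFBI, OAS3, EGLN3, PFKFB4 and GLUL lost their call in some settings, and FBP1 had a value above 0 after normexp.

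The labels do not say that replicate numbers pair samples, but same-numbered samples lay in 1 row of the slide. Their deviations correlated at -0.0109 (siCtrl and siBcat9), 0.0681 (siCtrl and siBcat10) and 0.229 (siBcat9 and siBcat10), not above 0.1 in every pair, so the numbers were not taken as pairs. With the number as a replicate block, the counts were 9576 (siBcat9), 8843 (siBcat10), 10060 (mean), 6001 (both siRNAs) and 4413 (between the siRNAs), and TBP was called. The slide block was not run, as all arrays lay on 1 slide.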

Other observations

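The tests of symbol families and the choice of lincRNA regions in this part were made after the data were seen, and the tests of scaling and dim genes were set before their results were seen.

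Gene symbols were grouped by their shared letters, and 29 of 242 such families of at least 8 genes passed in camera at the preset correlation, none with an estimated one. Of 9 measured RRP genes 7 fell (median log2 change -0.98, adjusted p = 0.00127; adjusted p = 0.673 with an estimated correlation), of 11 UTP genes 9 fell and 1 rose (-0.78, adjusted p = 0.000194; adjusted p = 0.673 with an estimated correlation), of 8 NOP genes 6 fell (-0.78, adjusted p = 0.00147; adjusted p = 0.673 with an estimated correlation), and of 10 EXOSC genes, subunits of the RNA exosome, 9 fell (-0.58, adjusted p = 0.000361; adjusted p = 0.673 with an estimated correlation). The RNA helicases named DDX fell in 19 of 33 cases and rose in 0 (-0.42, adjusted p = 2.69e-05; adjusted p = 0.673 with an estimated correlation), and the nucleoporins named NUP fell in 14 of 23 and rose in 2 (-0.52, adjusted p = 0.000194; adjusted p = 0.673 with an estimated correlation). Cytochrome P450 genes rose in 29 of 39 cases and fell in 1 (0.70, adjusted p = 3.79e-07; adjusted p = 0.673 with an estimated correlation), and UGT glucuronosyltransferases rose in 7 of 9 (0.83, adjusted p = 0.015; adjusted p = 0.79 with an estimated correlation). The medians of these families kept their sign under the 4 other scalings run (normexp, quantile, median of kept probes and the authors' table).

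The arrays also carry probes for lincRNA regions, with coordinates on hg19 as the files give them. Of 3571 such regions tested, 293 were higher and 117 lower with both siRNAs. In the mean comparison 623 were higher and 233 lower, against 1603 and 140 after normexp, 444 and 324 after quantile normalization, 489 and 276 with the median of kept probes, and 548 and 255 in the authors' table. The normexp offset can itself add higher calls among dim regions, and its share was not tested. Chosen after their values were seen, the largest shared falls were in the regions on chromosome 16 from 50682543 to 50683160 (log2 changes -2.44 and -2.97) and on chromosome 1 from 205404014 to 205407007 (-2.97 and -2.06). The largest shared rise was on chromosome 2 from 102597068 to 102606493 (2.88 and 2.64).

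More genes rose than fell in the mean comparison, 5910 against 4126. With the median change of all genes set close to 0, 10077 genes were called and 47.8% of them rose (exact binomial 95% interval 46.8% to 48.8%), but that step itself brings the balance towards equal numbers and so decides nothing. The share that rose was 69.4% after normexp, 52.8% after quantile normalization and 52.1% with the median of kept probes, and scaling stays open. Dim genes stay open too: among the 5951 called genes brighter than the median gene 53.6% rose (52.4% to 54.9%), against 66.5% of the 4085 dimmer ones. As genes are not independent, the binomial intervals given here are too narrow. No biological explanation was tested.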
